A study of Rattus norvegicus with 8 samples.

How the data were processed

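Nuclei of frozen fetal rat lung were sequenced as 8 libraries: 2 control, 3 hypoplastic and 3 hypoplastic with EV treatment, grouped and numbered per the labels. Per the labels' protocols, nuclei were extracted on an automated dissociator and taken through the 10x Genomics 3' assay, in which each captured RNA molecule carries a UMI, so that copies made by amplification count once. The matrices the authors deposited hold raw UMI counts per gene and barcode, not normalized. Per the submitters' processing notes they were made with Cell Ranger 6.0.0 on genome build rn6, while the file headers name version 6.0.1. Whether intronic reads were counted and which annotation release was used is not given in the sources used here. The assay reads the 3' ends of transcripts, and reads shared between near-identical genes or overlapping genes could have been split or dropped in the authors' counting.

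The deposited files hold 165853 barcodes and 32883 genes. The lowest total per barcode differed between libraries, from 747 to 1366 UMIs, so the authors' calling of nuclei had left different floors. Nuclei with at least 500 UMIs and 300 genes were kept, which removed 0 barcodes. Doublets, droplets with more than 1 nucleus, were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.008 per 1000 nuclei. It marked 11575 barcodes, which were left out, and 154278 nuclei were kept. The marked share was uneven: 1.43% and 1.54% in the controls, 17.8%, 10.8% and 7.07% in hypoplastic replicates 1, 2 and 3, and 1.56%, 2.49% and 14.9% in EV-treated replicates 1, 2 and 3. Scrublet set its score cutoff per library. It was 0.5947 to 0.718 in the controls and EV-treated replicates 1 and 2, and 0.3205 to 0.4065 in the others. The uneven share followed these cutoffs and need not reflect the number of doublets.

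The files give versioned Ensembl gene identifiers in both columns of the gene lists and do not pair them with symbols. Of the 32883 identifiers, 0 matched an entry in the rat gene table used here (assembly GRCr8). The marker lists for cell types, the gene lists for inflammation and other processes, the share of macrophages, the filter on mitochondrial genes and checks by sex-linked genes, all set before the data were examined, rest on symbols and were therefore not run. In place of lineages, numbered clusters were compared. Counts were scaled to 10000 UMIs per nucleus and log-transformed, 3000 variable genes were centred and scaled within each library, and the first 40 principal components and 20 nearest neighbours were used for Leiden clustering at resolution 1 (python-igraph 0.11.9). This gave 45 clusters; the 21 with at least 50 nuclei in every library, holding 86.6% of nuclei, were tested.

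UMI counts were summed per library over all nuclei (whole lung) and per cluster, with the library as the replicate. The sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, its own filter on low counts, all 8 libraries in a fit with a term per group, robust quasi-likelihood F test, Benjamini-Hochberg adjustment within each comparison and cluster, threshold 0.05). Sums entering the whole-lung fit ran from 33427828 to 63567351 UMIs and 18608 genes passed the filter. The common biological coefficient of variation between libraries of a group was 28.8%. Shares of nuclei were tested with the same model on counts of nuclei in the 44 clusters with at least 100 nuclei, and by exact two-sided permutation tests. CPM are UMI counts scaled to 1000000 per library after TMM scaling, or, for the sets of genes near 0 in some libraries, without it.

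The rule for named genes, set before the data were examined, took up to 10 genes each way per main comparison among those past the threshold with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups, and otherwise those with the smallest p as values. No gene met it, and as the files give no names only 4 identifiers are printed. The method was tested on simulated counts drawn from the real means, depths and spread. For hypoplastic against control, edgeR called 6% of genes changed 2-fold and 76% of those changed 4-fold, with 5 false calls among 18384 genes. For EV-treated against hypoplastic it called 17% and 83%, with 7 false calls. DESeq2 called 40% and 89% with 53 false calls in the first, and 54% and 94% with 51 in the second. The changed genes numbered 100 at each fold, so a larger part of DESeq2's calls than of edgeR's was false. In EV-treated against control lungs, where no gene was changed, DESeq2 gave 29 false calls and edgeR 0. DESeq2 counts and p-values are to be read with this limit. Shares were simulated with random class sizes and a preset spread, not with those of the data. Of 4 doubled classes 2 were called, and 0 others, which does not give the power for the real shares.

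Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, only the compared groups in the fit, each library left out in turn, doublets kept, at least 1000 UMIs and 500 genes per nucleus, and clustering without centring by library. They were set beforehand for whole lung or for lineages, and were applied to numbered clusters, shares and EV-treated against control lungs after seeing the data. Added after seeing the data were clustering at resolution 0.2, removal of the top 8% of doublet scores in every library, leaving out clusters 1 or 8, leaving out hypoplastic replicates 1 and 2 together, and a term for the state of 7 genes that parted the libraries. For the comparison of fold changes between the main comparisons, 20 data sets with unchanged groups were simulated and 100 random regroupings of the libraries drawn. Genome positions of genes are not given here.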

Results

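Single-nucleus RNA sequencing was performed on 8 samples of fetal rat lung in 3 groups: 2 control, 3 hypoplastic (underdeveloped, injured) and 3 hypoplastic samples treated with extracellular vesicles (EVs) of amniotic fluid stem cells. Extracellular vesicles are small membrane-bound particles that cells release. The sample labels place the lungs at embryonic day 21, and the series design at a point later on that day. Nothing in the labels says whether the samples of a group came from separate animals or litters. The p-values therefore measure only the spread between these samples, part of which may be technical. The libraries held 17293 to 24736 barcodes and 36663135 to 64619318 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule). Median depth ran from 1654 UMIs per nucleus in hypoplastic replicate 3 to 2216 in control replicate 1. The files give genes by Ensembl identifier and do not pair identifiers with names, so genes appear by identifier and cell populations as numbered clusters.

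The 3 hypoplastic libraries did not lie together (plot of library principal components). The first component of whole-lung log2 CPM (UMI counts scaled to 1000000 per library) took 44.7% of the variance and set hypoplastic replicate 1 at 112.4 and hypoplastic replicate 2 at 48.8, while the other 6 libraries lay between -34.6 and -21.2. Hypoplastic replicate 3 was among those 6. Its profile correlated across genes with control replicate 1 at r = 0.983, against 0.934 with hypoplastic replicate 1 and 0.958 with hypoplastic replicate 2 (genes are not independent replicates). No pair of libraries differed by as little as sampling noise: the smallest chi-square per degree of freedom over the pairs was 46.8.

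**Figure D1:**
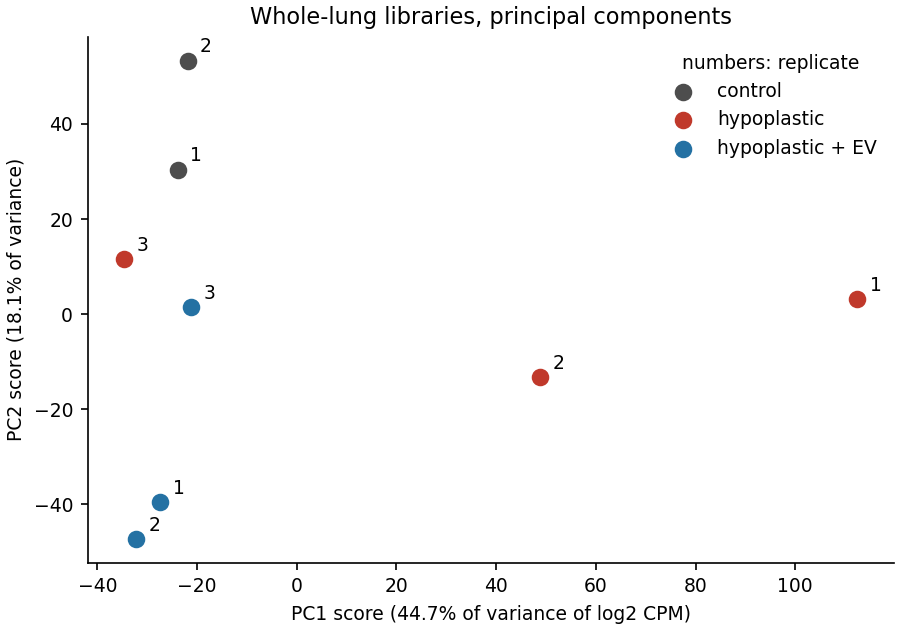
Scores of the 8 whole-lung libraries on the first (x axis) and second (y axis) principal component of log2 CPM, which took 44.7% and 18.1% of the variance. Points are libraries, coloured by group and numbered by replicate, and hypoplastic replicates 1 and 2 lie at 112.4 and 48.8 on the first component, apart from the other 6.

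A small set of genes was near 0 in some libraries and high in others. Of 37 genes with a gap of at least 4 log2 units between library levels, 22 were high only in hypoplastic replicates 1 and 2, where they summed to 5506 and 2878 CPM, against at most 48.9 CPM in each of the other 6 libraries. A set of 5 genes summed to 376 to 590.1 CPM in both controls, hypoplastic replicates 1 and 3 and EV-treated replicate 3, and to at most 1.52 CPM in hypoplastic replicate 2 and EV-treated replicates 1 and 2. A pair of genes did the opposite, with 2542 to 3130 CPM in those 3 libraries and 17.3 to 44.5 CPM in the other 5. These 7 genes parted libraries within the hypoplastic and EV-treated groups, and set no whole group apart from another. Such gaps argue against hypoplastic replicate 2 being a repeat library of the same lung as hypoplastic replicate 1 or 3. They argue likewise against EV-treated replicate 3 being a repeat of EV-treated replicate 1 or 2. Other pairs of a group, the controls included, are not parted by these genes. Both controls lay on the same side, so the division was uneven over the groups.

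**Figure D2:**
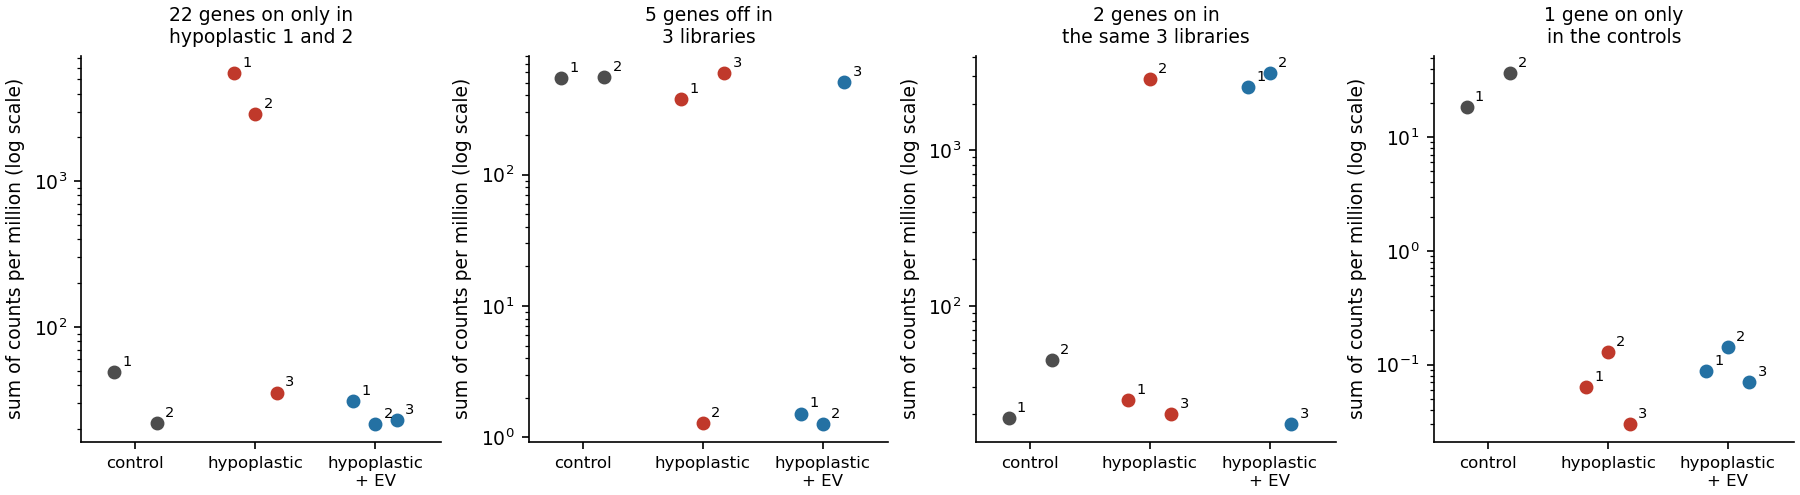
Summed CPM on log axes (y axes) of 4 sets of genes in each library, by group (x axes). Points are libraries numbered by replicate: 22 genes are high only in hypoplastic replicates 1 and 2, 5 genes are near 0 in hypoplastic replicate 2 and EV-treated replicates 1 and 2, a pair is high in those 3 libraries, and 1 gene is high only in the controls.

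The comparison of hypoplastic with control lungs asked what the injury changed in the fetal lung. Summed over all nuclei, 1 gene was lower in hypoplastic lungs and none was higher. ENSRNOG00000014118.5 stood at 27.2 ± 11.8 CPM (SD, n = 2) in control lungs and at 0.0731 ± 0.0499 CPM (SD, n = 3) in hypoplastic lungs, and at 0.101 ± 0.0389 CPM (SD, n = 3) in EV-treated lungs. It had 1162 and 1928 UMIs in the controls and 1 to 6 UMIs in each of the 6 other libraries, and the pooled counts put it 337-fold higher in control than in hypoplastic lungs (exact binomial 95% interval 183 to 703, counting error only). The gene with the smallest p among those higher in hypoplastic lungs did not pass the test: it lay at 13.4 ± 3.20 CPM (SD, n = 3) in hypoplastic lungs against 3.89 ± 1.19 CPM (SD, n = 2) in controls, a log2 fold change of 1.78 ± 0.30 (SE; adjusted p = 0.348, edgeR; 0.00886 without hypoplastic replicate 3, and 2.22e-05 by DESeq2), with every hypoplastic library above both controls.

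By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ENSRNOG00000014118.5 had a log2 fold change of -8.42 ± 0.51 (SE; adjusted p = 0.00157), and over the alternative settings its adjusted p ran from 6.88e-40 to 0.0631, the latter without hypoplastic replicates 1 and 2. No gene met the rule for named genes, which also asks for a mean log2 CPM of at least 3, and this gene was chosen because it made up the count. Of 18608 genes tested, 2349 had an unadjusted p under 0.05, and DESeq2 called 374 genes (297 higher, 77 lower in hypoplastic lungs). On simulated counts DESeq2 gave 53 false calls in this comparison, against 5 by edgeR. The libraries of the groups did not overlap for 4677 genes (25.1%; chance gives 20%), of which 549 were at least 2-fold higher and 328 at least 2-fold lower in hypoplastic lungs. Hypoplastic replicate 3 set the count of calls: without it edgeR called 819 genes (685 higher, 134 lower). The hypoplastic group was then replicates 1 and 2, which alone were high in the 22 genes above and lay apart on the first component. Whether such counts reflect the injury or what only these libraries share was not tested. This limit holds for every result in the text that leaves out hypoplastic replicate 3.

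Within clusters of nuclei, few genes differed between hypoplastic and control lungs by edgeR, and their direction depended on the setting. Of 21 clusters with at least 50 nuclei in every library, 6 held calls, 18 in all (3 higher, 15 lower in hypoplastic lungs), of 16 distinct genes. Some settings that called many more gave mostly higher ones (DESeq2 1684 higher and 587 lower, no filter on low counts 5498 and 1932, the replicate number as a block 2125 and 481). Others did not (30 higher and 412 lower without control replicate 1, 37 and 41 without hypoplastic replicates 1 and 2 together). Cluster 18 held 9 of them (2 higher, 7 lower). ENSRNOG00000014118.5 was lower in 3 clusters, 3, 4 and 20, with log2 fold changes of -8.71 ± 0.62, -8.42 ± 0.61 and -5.87 ± 0.65 (SE; edgeR adjusted p = 0.00427, 0.00169 and 0.0026). In cluster 20, ENSRNOG00000005094.7 fell from 782.2 ± 116.1 CPM (SD, n = 2) in controls to 297 ± 14.3 CPM (SD, n = 3) in hypoplastic lungs, a log2 fold change of -1.45 ± 0.22 (SE; edgeR adjusted p = 0.0424). It was chosen after its values were seen, as the gene called in opposite directions in both main comparisons.

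The median size of the 18 log2 fold changes was 2.46. The sum of calls rested on single libraries: it was 12874 without hypoplastic replicate 3 (8733 higher, 4141 lower), 0 without hypoplastic replicate 2 (23900 at an unadjusted p under 0.05, where DESeq2 was not run), 442 without control replicate 1, 5 without control replicate 2, and 8, 6 and 7 without EV-treated replicates 1, 2 and 3. The 9 calls of cluster 18 ranged from 0 to 506 as each library was left out, and moved by over 1.5 times for each library but hypoplastic replicate 1 (7 without it). ENSRNOG00000014118.5 was past the threshold in these 3 clusters as each library was left out, except without hypoplastic replicate 2 (adjusted p up to 0.196) and, in cluster 20, without control replicate 2 (adjusted p = 0.369). The fall of ENSRNOG00000005094.7 was past the threshold without hypoplastic replicate 1 or 3 and not without any 1 of the other 6 libraries (adjusted p up to 0.741). It was not past it with doublets kept either (adjusted p = 0.0887), median-ratio size factors (0.0556) or only the compared groups in the fit (0.403). By DESeq2 its adjusted p was 4.3e-06.

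The comparison of EV-treated with untreated hypoplastic lungs asked what the vesicles changed in injured lungs. Summed over all nuclei, no gene passed the test by edgeR. The genes with the smallest p in each direction are given as values. ENSRNOG00000005905.8 lay at 317 ± 53.6 CPM (SD, n = 3) in hypoplastic and 117 ± 14.9 CPM (SD, n = 3) in EV-treated lungs, with controls between them at 195 ± 11.3 CPM (SD, n = 2). ENSRNOG00000002273.6 lay at 32.5 ± 6.58 CPM (SD, n = 3) in hypoplastic, 33.8 ± 4.59 CPM (SD, n = 2) in control and 82.2 ± 11.3 CPM (SD, n = 3) in EV-treated lungs. For both genes each of the 3 EV-treated libraries lay beyond each of the 3 hypoplastic ones.

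These 2 genes had log2 fold changes of -1.45 ± 0.17 and 1.34 ± 0.19 (SE), each with an edgeR adjusted p of 0.283, which ran up to 0.698 over the alternative settings. Both were past the threshold by DESeq2 (adjusted p = 1.06e-08 and 4.1e-06) and by edgeR without hypoplastic replicate 3 (0.00231 and 0.00359). Of 18608 genes tested by edgeR, 2438 had an unadjusted p under 0.05. DESeq2, run on 26269 genes without edgeR's filter on low counts, called 452 (147 higher, 305 lower in EV-treated lungs). On simulated counts it gave 51 false calls in this comparison, against 7 by edgeR. Among edgeR's 18608, the groups' libraries did not overlap for 3077 genes (16.5%, where chance gives 10%). Of these, 372 were at least 2-fold higher and 193 at least 2-fold lower in EV-treated lungs. Without hypoplastic replicate 3, so with hypoplastic replicates 1 and 2 as the whole group, edgeR called 1227 genes (394 higher, 833 lower). Whether EVs or what only those libraries share gave this count was not tested. Without hypoplastic replicate 2 edgeR called 1.

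**Figure D3:**
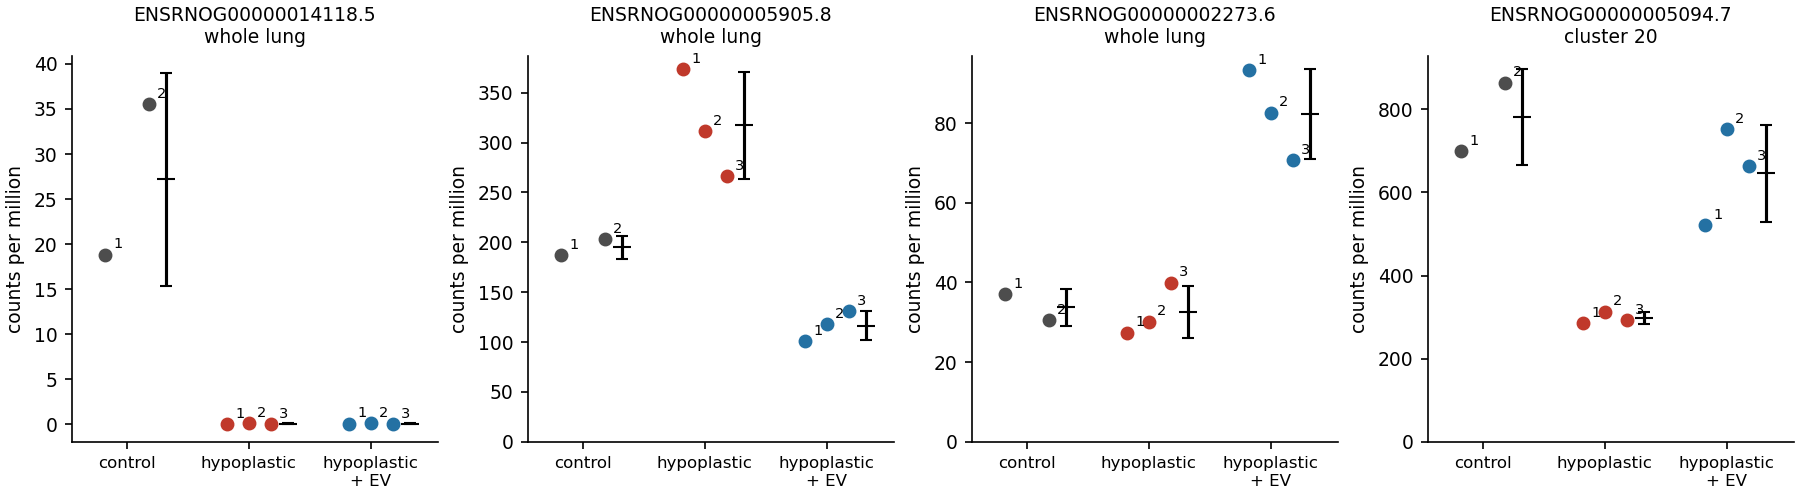
CPM (y axes) of 4 genes in each library, by group (x axes). Points are libraries numbered by replicate, and bars show the group mean ± SD (n = 2, 3 and 3); ENSRNOG00000014118.5 is near 0 in all 6 injured lungs, and ENSRNOG00000005094.7 in cluster 20 is lowest in the 3 hypoplastic libraries.

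Within clusters, edgeR made 32 calls between EV-treated and hypoplastic lungs (18 higher, 14 lower) of 31 distinct genes, in 6 of the 21 clusters. Their edgeR adjusted p ran from 0.0168 to 0.0451. As in the comparison with controls above, p was adjusted within each cluster and not across the 21. Settings that called many more gave mostly lower ones in EV-treated lungs (DESeq2 787 higher and 1574 lower, no filter on low counts 2903 and 5747, the replicate number as a block 311 and 788, the stricter nuclei filter 38 and 78). Cluster 11 held 13 of these calls (10 higher, 3 lower), and clusters 20 and 24 held 7 each (4 higher, 3 lower). By DESeq2 these 3 clusters had 47 higher and 82 lower, 52 and 71, and 92 and 34, so the balance of the sums did not hold in each cluster. In cluster 20, ENSRNOG00000005094.7 rose from 297 ± 14.3 CPM (SD, n = 3) to 646 ± 116.4 CPM (SD, n = 3), a log2 fold change of 1.21 ± 0.20 (SE; edgeR adjusted p = 0.0411). Controls lay at 782.2 CPM. The gene was picked for its calls in opposite directions, so a move back towards the controls was fixed by that choice. In the same cluster ENSRNOG00000005905.8 fell by 1.42 ± 0.24 on the log2 scale (SE; edgeR adjusted p = 0.0411). The sizes of the 32 log2 fold changes ran from 0.99 to 3.03.

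Scrublet had called 38.2% of the barcodes nearest to cluster 20 doublets, which were left out, against 17.6% in cluster 24 and 7.60% in cluster 11. With doublets kept, cluster 20 had 0 calls in place of 7, and its calls of ENSRNOG00000005094.7 and ENSRNOG00000005905.8 had an adjusted p of 0.0722 and 0.0708. With median-ratio size factors it had 2, and both genes were at 0.0507. With only the compared groups in the fit it had 0, and both were at 0.1. By DESeq2 both genes were past the threshold (adjusted p = 4.6e-05 and 0.000112). The sum over clusters was 16307 without hypoplastic replicate 3 (6589 higher, 9718 lower), 4 without either control replicate 1 or control replicate 2, and 6, 2 and 12 without EV-treated replicates 1, 2 and 3. The calls of clusters 11, 20 and 24 each rested on single libraries too, with ranges of 0 to 644, 0 to 701 and 0 to 826 as each library was left out. Only leaving out hypoplastic replicate 1 kept a count within 1.5 times, at 5 in clusters 20 and 24, while cluster 11 then had 1. The rise of ENSRNOG00000005094.7 was past the threshold without hypoplastic replicate 3 and not without any 1 of the other 7 libraries (adjusted p from 0.0524 to 0.358), and the fall of ENSRNOG00000005905.8 was past it without hypoplastic replicate 1 or 3 and not without any 1 of the other 6 (adjusted p up to 0.374).

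Compared with control lungs, EV-treated lungs had 1 gene lower and none higher, summed over all nuclei. The gene was ENSRNOG00000014118.5 (edgeR adjusted p = 0.00175), 270-fold higher in control lungs by pooled counts (exact binomial 95% interval 161 to 494, counting error only). Without EV-treated replicate 1 its adjusted p was 0.0519, so that edgeR called 0 genes (978 at an unadjusted p under 0.05); without hypoplastic replicate 2 it called 2, and DESeq2 with all libraries called 263. Over the 21 clusters there were 9 calls (1 higher, 8 lower) in 6 clusters. The count did not hold, and this balance did not in some settings that called many more: 72 higher and 107 lower by DESeq2, 618 and 625 with no filter on low counts, 276 and 258 with only the compared groups in the fit, and 408 and 361 without hypoplastic replicates 1 and 2 together. Leaving out each library moved that sum by over 1.5 times: it was 220 without control replicate 1 (6 higher, 214 lower), 3 without control replicate 2, 33, 31 and 79 without hypoplastic replicates 1, 2 and 3, and 4, 3 and 4 without EV-treated replicates 1, 2 and 3.

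The share of nuclei in each cluster addressed whether injury or treatment altered the makeup of the lung. Cluster 5 held 8.63% ± 4.00 (SD, n = 3) of nuclei in hypoplastic, 2.67% ± 1.13 (SD, n = 2) in control and 4.69% ± 0.30 (SD, n = 3) in EV-treated lungs. Hypoplastic replicates 1 and 2, at 11.2% and 10.6%, carried the hypoplastic mean, and hypoplastic replicate 3 held 4.03%. Without hypoplastic replicates 1 and 2 the log2 ratio of EV-treated to hypoplastic lungs turned from -0.88 to 0.22. Cluster 8 held 18.3% of nuclei in hypoplastic replicate 1 and 4.28% in hypoplastic replicate 2, and at most 0.532% in each of the other 6 libraries; its nuclei held 26.6% and 12.5% of the UMIs of the 22 genes high in hypoplastic replicates 1 and 2. Cluster 9 held 15.2% in control replicate 2 and at most 1.90% in each of the others. Cluster 38, a small one, held 0.291% ± 0.0869 (SD, n = 3) in EV-treated against 0.0551% ± 0.0181 (SD, n = 3) in hypoplastic and 0.114% ± 0.0667 (SD, n = 2) in control lungs.

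None of 44 clusters changed in share by edgeR in any of the 3 comparisons; 5, 4 and 3 had an unadjusted p under 0.05 (hypoplastic against control, EV-treated against hypoplastic, and EV-treated against control), and DESeq2 was not run on shares. The smallest adjusted p was 0.0871, for cluster 38 between EV-treated and hypoplastic lungs, a log2 ratio of 2.39 ± 0.54 (SE), and ran from 0.0534 to 0.367 over its alternative settings. An exact two-sided permutation test of that share gave p = 0.1, the smallest that 3 samples against 3 allow. Without hypoplastic replicate 3, 2 clusters passed between EV-treated and hypoplastic lungs (1 higher, 1 lower).

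**Figure D4:**
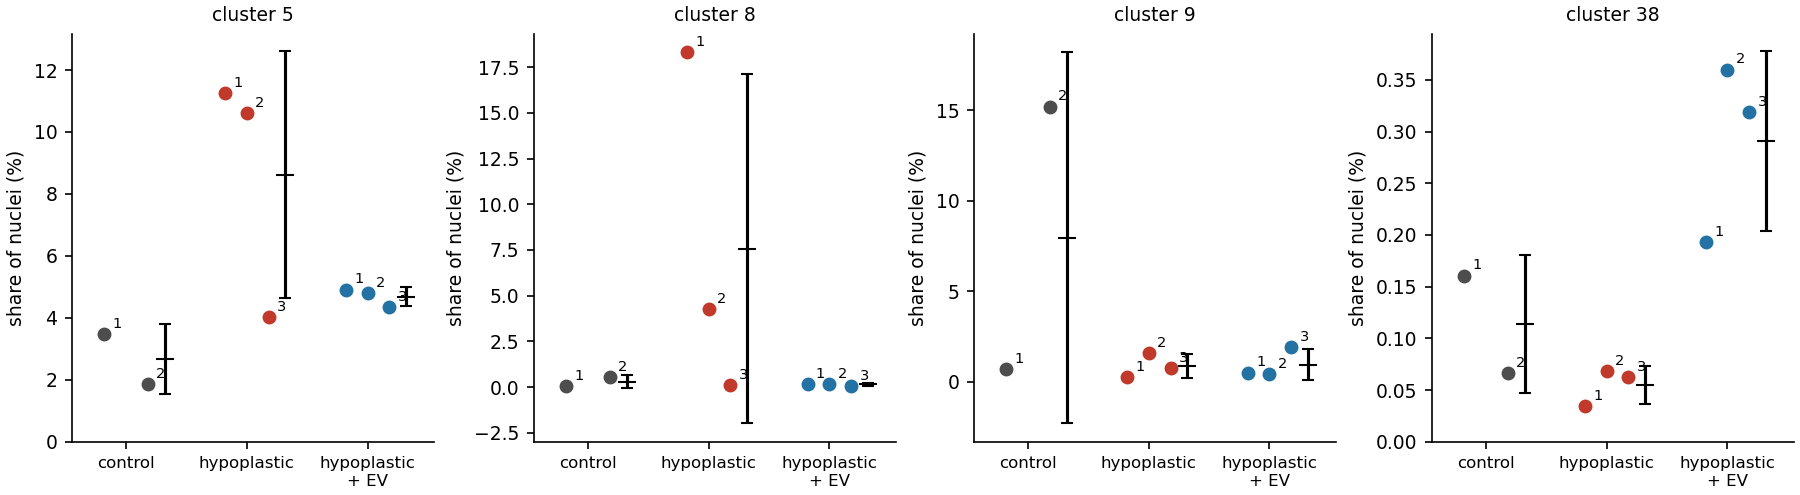
Share of nuclei in percent (y axes) of clusters 5, 8, 9 and 38 in each library, by group (x axes). Points are libraries numbered by replicate and bars show the group mean ± SD (n = 2, 3 and 3), which reach below 0 where 1 library holds most of a cluster; cluster 8 holds 18.3% of hypoplastic replicate 1, and cluster 9 holds 15.2% of control replicate 2.

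Whether EV treatment moved genes opposite to the injury was addressed by setting the fold changes of the main comparisons side by side. Across 18608 genes the log2 fold changes of hypoplastic against control and of EV-treated against hypoplastic lungs correlated at r = -0.69. Both comparisons use the 3 hypoplastic libraries, and 20 simulated data sets with unchanged groups gave a mean of -0.44 (range -0.47 to -0.42). The covariance was -0.346 against a simulated -0.078, a difference of -0.268. The simulation drew each gene independently with the same spread in all groups, while the 3 real hypoplastic libraries lay far apart. It therefore cannot tell whether r and the covariance go beyond those of unchanged groups with such a spread. At an unadjusted p under 0.05, 574 genes were higher in hypoplastic lungs and then lower with EVs, where the simulation gave 67.3 and independent lists would share 122.7. Another 153 were lower and then higher, where these were 101.2 and 41.2. Both comparisons moved 21 genes the same way, where the simulation gave 3.95 (range 0 to 7). It thus gave fewer genes than were observed in either kind of move, and its counts are no firm measure of an excess of opposite moves.

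No gene passed the adjusted edgeR threshold in opposite directions summed over all nuclei, and 1 did within a cluster, ENSRNOG00000005094.7 in cluster 20. From differences of mean log2 CPM, r was -0.60, and 16 of 100 random regroupings of the 8 libraries gave an r at least as negative (range -0.85 to 0.09). The simulation shared the hypoplastic libraries too, so sharing alone does not give the excess over it. Part or all of that excess may come from the wide spread of these libraries or from genes that vary together, which it did not draw. The 3 hypoplastic libraries are too few to split into sets of 2.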

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

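Alternatives for clusters and shares, for EV-treated against control lungs, leaving out hypoplastic replicates 1 and 2 together, leaving out cluster 1 or 8, the top 8% of doublet scores, the 7-gene term and resolution 0.2 were chosen after seeing the data. Alternatives set beforehand for lineages, gene lists, the macrophage share and the mitochondrial part of the stricter filter were not run, since they need gene symbols. Unless a cause is given, the cause was not tested. In whole lung, hypoplastic against control, EV-treated against hypoplastic and EV-treated against control gave 1, 0 and 1 genes by edgeR (2349, 2438 and 2029 at an unadjusted p under 0.05), 374, 452 and 263 by DESeq2, and 0, 1 and 5 without hypoplastic replicates 1 and 2, where fewer samples were left; the lone hypoplastic library is then assumed to vary like the other groups. Only the compared groups in the fit gave 4 in the last comparison. Leaving out each library gave 1 to 819, 0 to 1227 and 0 to 2, with the highest of the first 2 ranges without hypoplastic replicate 3. Size factors, no filter, doublet and nuclei filters, leaving out a cluster and the 7-gene term left these 3 counts as they were.

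Summed over clusters, hypoplastic against control (18 calls) and EV-treated against hypoplastic (32 calls) gave 2271 and 2361 by DESeq2, 7430 and 8650 with no filter, 9 and 3 with only the compared groups, 13 and 9 at resolution 0.2, 78 and 165 without hypoplastic replicates 1 and 2, and 0 and 1 with clustering not centred by library, where fewer clusters (3) could be tested. Keeping doublets gave 9 in the first, and the stricter nuclei filter gave 116 in the second. Leaving out each library gave 0 to 12874 and 2 to 16307. Clusters changed in share numbered 0 in both under all 14 alternatives, except that leaving out each library gave 0 to 2 between EV-treated and hypoplastic lungs. The log2 ratio of the share of cluster 8 turned to -1.63 (hypoplastic against control) and 0.56 (EV-treated against hypoplastic), and that of cluster 5 to 0.22 (the latter), without hypoplastic replicates 1 and 2, the libraries that held most of cluster 8. The correlation between the main comparisons ran from -0.79 to -0.49 (without hypoplastic replicate 1) over the 10 alternatives. Its sign says nothing, since unchanged groups that share the hypoplastic libraries gave -0.44 on average with all libraries, and none were simulated for the alternatives.

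With the replicate number as a block, whole-lung counts were 1, 0 and 1, and the sums over clusters rose to 2606 and 1099. Whether the numbers pair the samples was not settled. Same-numbered hypoplastic and EV-treated libraries deviated from their group means with correlations of -0.02, 0.17 and 0.01. Not every library correlated best with its own number. Such correlations over all genes cannot exclude a pairing by litter or batch. Depth limits the small clusters: 6129 genes could be tested in cluster 29 against 18608 in whole lung, where a 2-fold change was called for 6% and 17% of simulated genes in the main comparisons.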

Other observations

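The tests of free RNA in the sets of 22 and 5 genes and the count of splits over clusters were written down before their values were seen, and every other test in this part was chosen after the result was seen. The genes behind these patterns were picked from the same libraries, so what follows are hypotheses.

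A set of 22 genes was high in hypoplastic replicates 1 and 2 alone, at 0.551% and 0.288% of all UMIs, 113-fold and 58.9-fold above the highest other library. They were present in all 21 tested clusters, at 1902 to 9347 CPM in hypoplastic replicate 1 and 1043 to 6238 CPM in hypoplastic replicate 2. Both were highest in cluster 1, the shallowest tested (median 1026 UMIs per nucleus over all libraries), and lowest in cluster 15, the deepest (5242). The order was not strict: cluster 17, at 1486 UMIs, held 4073 and 2242 CPM. Log10 counts of the genes in a cluster correlated with those of its library, which include them, at a median of 0.936 (lowest 0.794). Nuclei of cluster 8 do not account for most of them, since they held 26.6% and 12.5% of these UMIs. Hypoplastic replicate 3 lay at 0.726 times the highest control or EV-treated library. The genes were picked for being low there, so this value cannot test a cause in the hypoplastic group as a whole. Free RNA from another source stays open: it would weigh most in nuclei with few UMIs, and the share of these genes in the 25% of nuclei with the fewest UMIs over that in the 25% with the most had a median over clusters of 1.39 in hypoplastic replicate 1 and 1.72 in hypoplastic replicate 2, where 100 random sets of equally abundant genes reached 1.42 and 1.56 at most. Hypoplastic replicate 1 thus missed the bound of 1.5 set beforehand. The high level in the shallowest cluster and the like mix of genes between clusters go with free RNA, but do not exclude expression. Free RNA and expression by these lungs' own nuclei therefore cannot be told apart. No source tissue was tested because the genes are unnamed.

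A set of 5 genes was near 0 in hypoplastic replicate 2 and EV-treated replicates 1 and 2, and a pair of other genes was high in just those 3 libraries. A cell type present in only some libraries would part them in some clusters, but both sets parted the same libraries in 21 of 21 tested clusters. For the 5 genes free RNA is also argued against, since they were no more frequent in nuclei with few UMIs: the median ratio was at most 0.932 over the 5 libraries with these genes on. The pair was not tested for free RNA. Its level differed between clusters in the 3 libraries where it was high, at 122 to 156 CPM in cluster 1 and 3513 to 4298 CPM in cluster 2. A fixed difference between individual fetuses, such as sex or genotype, would act in every nucleus and stays possible; it was not tested, since the labels name neither and the genes are unnamed.

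ENSRNOG00000014118.5, the 1 gene called in whole lung between hypoplastic and control lungs, was nearly absent from all 6 injured lungs, with at most 6 UMIs in each. It was higher in both controls than in every other library in 20 of 21 tested clusters, which argues against a cell type that only the controls held. Its level differed between clusters by 4.94 times in control replicate 1 and 5.24 times in control replicate 2, over clusters with at least 20 of its UMIs. Depth also differs between clusters, so this range alone does not decide on free RNA. Clusters 2 and 3 had like median depths over all libraries, 2877 and 2727 UMIs per nucleus. The gene lay there at 9.3 and 45.6 CPM in control replicate 1. In control replicate 2 it lay at 15.1 and 79.3 CPM. This argues against free RNA spread evenly over nuclei. A sequence difference between the control and the injured lungs and an effect of the injury cannot be told apart. Every library outside the controls is also an injured one, and the labels give no litter.

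The 6 hypoplastic and EV-treated libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes in whole lung by edgeR (2438 at an unadjusted p under 0.05; 452 by DESeq2), and the highest of the others gave 11. Over the clusters the real split gave 32 calls, and 2 of the 10 splits, the real one included, gave as many; the highest of the others gave 180. That split set hypoplastic replicates 1 and 3 and EV-treated replicate 3 against the other 3, as the 7 genes above do. These genes were picked for parting just those libraries and account for most of its calls: besides them it gave 4 genes in whole lung and 44 calls over clusters, against 0 and 32 in the real split, so whether other genes follow the same division of the samples stays open.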
